A study of Mus musculus with 16 samples.

How the data were processed

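The series holds 16 mouse samples, of which 13 are RNA libraries and 3 are chromatin immunoprecipitation samples. Per the labels, the RNA libraries come from OG2 embryonic stem cells (ESC) at passage 5, OG2 embryonic fibroblasts (MEF) at passage 2 and MEF on day 3 of reprogramming with Klf4, Sox2 and c-Myc (KSM). RNA was extracted with Trizol and libraries were made with a TruSeq kit, per the labels' protocols. The immunoprecipitation samples are c-Jun in ESC after 36 h of doxycycline, an input of ESC and c-JunDN on day 3 of reprogramming. The antibody is labelled c-Jun for the c-JunDN sample too. The input sample was not analysed here.

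The authors aligned RNA reads to mm9 with Bowtie2 2.2.3 after bcl2fastq 2.15.0.4 and quantified genes with RSEM 1.1.21, per the submitters' processing notes. The expected counts are the authors' RSEM values per gene, not whole numbers, and were rounded here. The second value of 12 deposited libraries is a fraction of transcripts per gene, made by the authors with RSEM, that sums to 1. It was scaled to TPM here as an alternative. The MEF Oct4 library was deposited with RSEM expected counts, TPM and FPKM computed by the authors on Ensembl genes, and the FPKM values were not used here. The authors deposited peaks on mm9 with a score per peak, and the peak names begin with MACS. Whether the input was used in calling peaks is not stated.

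The 12 other RNA libraries share 20325 RefSeq-based gene names. The MEF Oct4 library has 27729 Ensembl IDs, of which 27247 have a symbol, and 17964 of those symbols are RefSeq-based names. With synonyms, 19643 names were shared, 1679 of them through a synonym, and they hold 96.73% of the 1896522 expected counts of that library. Comparisons with the MEF Oct4 library use these shared genes for both sides. Of 423 names in the fixed gene lists, 3 were absent (Hmgcs1, Xist and Tsix) and 5 were found through a synonym. No 2 RNA libraries held identical values.

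Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, and the scaled values are called CPM. Changes are log2 ratios of CPM plus a pseudocount of 1. A gene was measured in a comparison with at least 5 CPM in 1 of the 2 libraries, and called higher or lower at 2-fold or more. The ratio of 2 libraries carries an exact conditional binomial 95% interval, which covers counting error only. A gene with 0 counts on one side is given as at least a fold against a floor of 3 counts, and no fold is given with both sides at or under the floor. Ratios that rest on 1 to 3 counts are given with their interval. The TMM factors were 0.922 (WT ESC), 1.094 (ESC with doxycycline), 0.953 (without), 0.766 (WT MEF), 0.987 (DR), 1.02 (c-Jun), 0.986 (c-JunDN), 1.02 (Jdp2), 1.02 (Oct4), 1.063 (KSM with DR), 1.044 (with Oct4), 1.069 (with c-JunDN) and 1.129 (with Jdp2). Between 13528 and 15901 genes were detected per library.

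With 1 library per group no test across replicates was possible, and no p-values are given. The 8 comparisons set induced against uninduced ESC, each of 4 MEF libraries against DR, and each of 3 KSM libraries against KSM with DR. The uninduced line was also set against WT ESC, and DR against WT MEF. Lists were summarised by their median and its percentile among 10000 random lists drawn from the same 20 expression bins. The percentile describes these libraries and is not a significance across animals or cultures. A list with under 5 measured members has no percentile. The 24 lists are factors, pluripotency, mesenchymal, epithelial, AP-1 family, endoderm, mesoderm, ectoderm, trophectoderm, cell cycle, p53 and senescence, protease and inflammatory, interferon response, immediate early, smooth muscle and contractile, cholesterol synthesis, glycolysis, chromatin regulators, macrophage, endothelial, skeletal muscle, erythroid, keratinocyte and sex chromosome. Identity genes differ at least 8-fold between WT MEF and WT ESC. Correlations between changes were set beside the covariance of 20 simulations of unchanged groups, with dispersions of 0.0066 (MEF) and 0.00528 (KSM) from genes of at least 50 CPM. Peaks were called shared with 1 bp of overlap, and shifted lists gave the chance level.

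Named genes follow a rule. They are the factors, up to 3 measured members of each list with the largest change, and the 6 highest and 6 lowest genes that also passed 2-fold against the second control. Unnamed gene models and pseudogenes were left out, and 5 peaks per list with the highest scores are given. Where a list is summarised over several comparisons, the 3 members with the largest mean absolute change are named. Some genes that the rule names are not reported here. Cdx2 in ESC and Twist2 in KSM lie outside this rule and were chosen after their values were seen. The groups, comparisons, lists, thresholds and the alternatives below were set before the data were examined. The pair of c-Jun in MEF and c-Jun in ESC and 2 alternatives for the Oct4 library were added afterwards. So were the bands for moved values, namely the bootstrap 95% interval over members for medians and the Fisher interval over genes for correlations, and the limits for a reversal and for setting a result apart.

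The alternatives were median-ratio size factors of DESeq2 1.42.0, total counts, TPM, a pseudocount of 5, no low filter, the WT library as control, both controls together, 32-fold identity genes, at least 20 CPM for correlations, and for peaks a 50% reciprocal overlap, midpoints within 1 kb and the upper part by score. Genes near peaks were not analysed here. On simulated data with known changes, 4-fold changes were recovered in 96.0% (c-Jun in ESC), 99.0% (c-Jun in MEF), 99.0% (Oct4 in KSM) and 98.0% (c-JunDN in KSM). Unchanged genes passed 2-fold in 0.918%, 1.47%, 0.515% and 0.562%. The simulated ESC used the KSM dispersion. Each dispersion came from 1 pair of libraries, c-JunDN and DR in MEF and c-JunDN and Jdp2 in KSM. The shares are therefore no rate of false calls between cultures, and none could be estimated without replicates. Between the real controls, 20.0% of genes passed 2-fold for DR against WT MEF and 24.5% for uninduced against WT ESC. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.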

Results

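RNA was sequenced from mouse embryonic stem cells (ESC), mouse embryonic fibroblasts (MEF) and MEF on day 3 of reprogramming with Klf4, Sox2 and c-Myc (KSM). The 13 RNA libraries comprise 3 of ESC, 6 of MEF and 4 of the KSM mixture, with 1 library per group. The ESC libraries are a wild-type (WT) culture and a line carrying a doxycycline-inducible c-Jun, taken at 36 h with or without doxycycline. The MEF libraries are a WT culture and cultures given c-Jun, its dominant-negative form c-JunDN, Jdp2, Oct4 or the control vector DR. The KSM libraries received DR, Oct4, c-JunDN or Jdp2 in addition. Chromatin immunoprecipitation gave a list of 3100 c-Jun peaks in induced ESC and a list of 1340 c-JunDN peaks on day 3 of reprogramming. With 1 library per group no difference has a replicate check, and each count below compares libraries.

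The WT libraries were sequenced much deeper than the others. Expected counts summed to 12173100 in WT ESC and 21415021 in WT MEF. They summed to 2696027 with and 2322922 without doxycycline in the inducible ESC line. The MEF libraries held 2094306 (DR), 1961313 (c-Jun), 2472474 (c-JunDN), 1961268 (Jdp2) and 1834424 (Oct4, on shared genes). The KSM libraries held 2556709 (DR), 3440917 (Oct4), 2976932 (c-JunDN) and 2623566 (Jdp2). A count of 3 corresponded to between 0.835 and 1.6 CPM in the libraries other than WT.

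Within each cell type, each introduced factor's gene was far above the control in the library labelled with it. Jun, the gene of the AP-1 subunit c-Jun, stood at 2015.1 CPM in induced ESC against 21.2 CPM without doxycycline, a 94.9-fold difference (95% interval 71.3 to 129.3). In MEF, Jun reached 11964.6 CPM with c-Jun and 3967.9 CPM with c-JunDN, against 88.5 CPM with DR. Jdp2, which encodes a repressor that dimerises with Jun proteins, reached 7226.0 CPM with Jdp2 against 76.9 CPM. Pou5f1, the gene of the pluripotency factor Oct4, reached 10413.9 CPM with Oct4 against 2.59 CPM. The levels were lower in the KSM cells, at 1710.5 CPM for Pou5f1, 366.2 CPM for Jdp2 and 352.2 CPM for Jun in the libraries given each factor. Sox2, Klf4 and Myc were at 511.1 to 915.7 CPM in the 4 KSM libraries. The counts cannot tell introduced from endogenous transcripts.

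**Figure D1:**
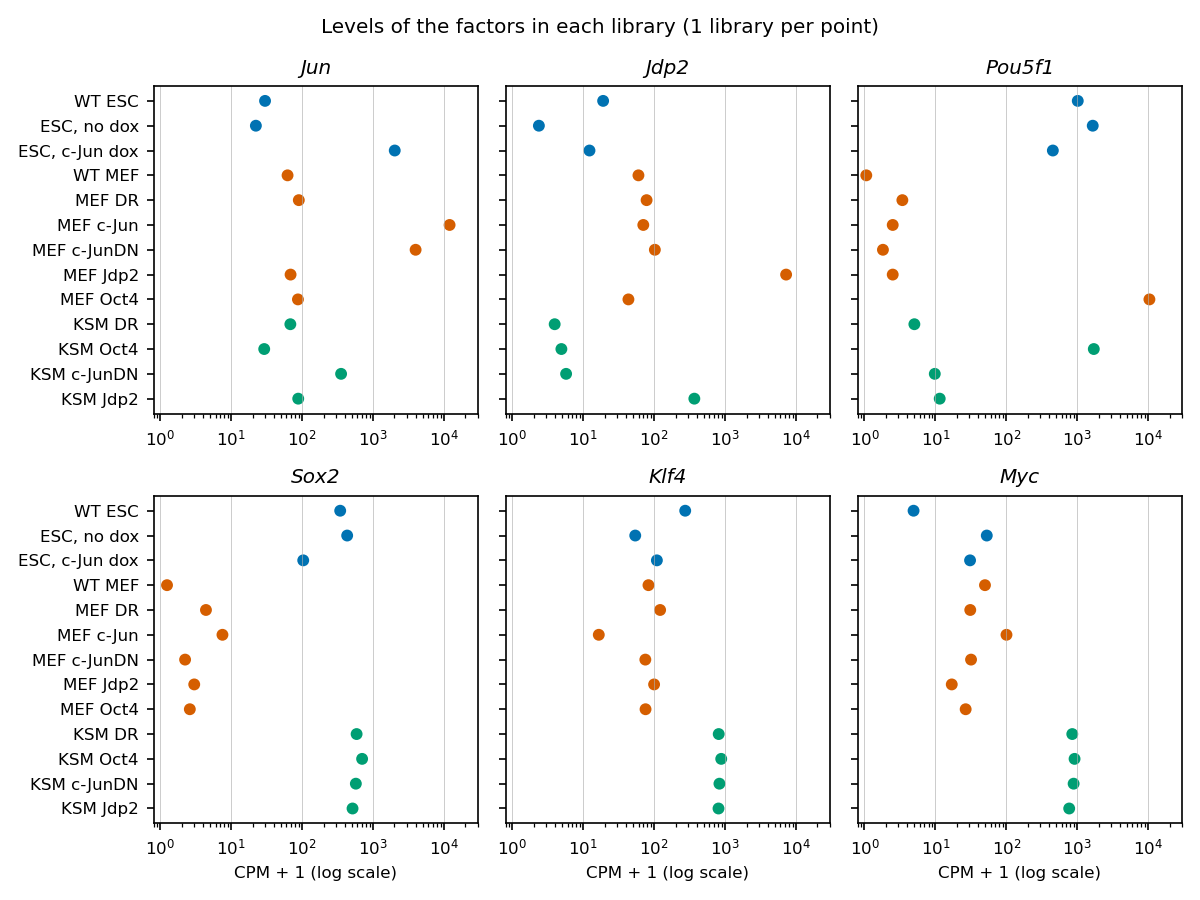
Level of the 6 factor genes (CPM plus 1, log axis) in each of the 13 RNA libraries, 1 point per library, with ESC in blue, MEF in orange and KSM in green. Jun is highest in the MEF c-Jun library (11964.6 CPM), Jdp2 in the MEF Jdp2 library (7226.0 CPM) and Pou5f1 in the MEF Oct4 library (10413.9 CPM).

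Induction of c-Jun in ESC addressed how this factor moves ESC away from pluripotency. Most pluripotency genes fell, while most measured trophectoderm, epithelial, mesenchymal, protease and AP-1 genes rose within 36 h. Of 11133 measured genes, 2392 were at least 2-fold higher and 2108 at least 2-fold lower than without doxycycline. The counting interval excluded no change for 2369 and 2093 of them. The largest rises were in Tgm2, a transglutaminase that cross-links matrix (log2 8.58), Tgfbi, a secreted matrix protein (8.42), Msln, the mesothelial surface protein mesothelin (8.35), and S100a6, a calcium-binding protein (8.28). Msln had 1 count without doxycycline, and its ratio was 1045.6 (187.4 to 41329.4). Gal, a neuropeptide gene absent without doxycycline, was at least 157.5-fold higher.

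Of 28 measured pluripotency genes, 25 fell, 2 rose and 1 did neither, with a median log2 change of -2.58, below all 10000 random lists. Large falls were in Nr0b1, an orphan nuclear receptor gene of ESC (-4.34) and L1td1, which encodes an RNA-binding protein of ESC (-4.10). Pou5f1 fell 3.66-fold (3.44 to 3.90) and Sox2 4.19-fold (3.68 to 4.79), while Klf4 rose 2.04-fold (1.64 to 2.54). Among all genes, Otx2, a homeobox gene of the epiblast and forebrain (-5.40), Lefty2, a Nodal antagonist (-4.44), and Tdh, the ESC threonine dehydrogenase (-4.40), were among the lowest. The names Nanogpd, Amd2 and Rangrf also ranked among the lowest (-6.11, -5.53 and -5.44), but reads could be split with related gene copies or overlapping genes, so these are uncertain.

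Trophectoderm genes showed the highest median of the larger lists. Of 12 measured, 11 rose and 1 did neither, with a median of 3.44. Against WT ESC, 9 of 12 measured rose and none fell (3.08). Hand1, a transcription factor of trophoblast giant cells, rose 147.8-fold (63.1 to 456.1), the placental gene Plac1 at least 26.3-fold and the homeobox gene Esx1 52.3-fold (20.2 to 193.4). Cdx2, a trophectoderm regulator, was at 2.37 CPM with and 4.52 CPM without doxycycline. Of 22 epithelial genes, 14 rose, 3 fell and 5 did neither (median 1.35), led by the simple-epithelium keratins Krt19 (7.09), Krt8 (6.51) and Krt18 (5.66). All 3 measured keratinocyte markers rose (median 4.36), among them Sfn (4.36) and Krt6a, at least 70.3-fold. Most of the keratinocyte list was not measured. A gene low without doxycycline is measured only if it is high enough in the induced library, so this count leans towards rises. So do those of other lists with members low without doxycycline, among them trophectoderm, endoderm and interferon response. Of 8 endoderm genes, 7 rose and 1 did neither (2.39), led by the basement-membrane collagens Col4a2 (4.55) and Col4a1 (3.88).

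Of 23 measured mesenchymal genes, 19 rose, 1 fell and 3 did neither, with a median of 2.49. Col1a1, a fibrillar collagen, rose 74.4-fold (44.2 to 136.5), Loxl2, a lysyl oxidase that cross-links collagen, 58.4-fold (43.4 to 80.5), and the hyaluronan receptor gene Cd44 265.9-fold from 2 counts (73.3 to 2200.0). WT ESC held collagens at higher levels than the uninduced line. Against WT ESC, Col1a1 was 0.09 higher on the log2 scale, and of 29 mesenchymal genes 12 rose and 10 fell, with a median of 0.19. Contractile genes rose in 9 of 13, with 1 lower (median 1.72), among them the intermediate filament gene Des (5.05) and the tropomyosin Tpm1 (3.22).

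Of 14 AP-1 genes, 11 rose, including Jun, and 3 did neither (2.29). Fosl2 rose 656.3-fold from 1 count (117.5 to 25953.0) and Fosl1 at least 24.8-fold. Of 13 protease and inflammatory genes, 12 rose and 1 fell (2.88), among them the cytokine Il11, at least 113.0-fold, and the macrophage growth factor Csf1, 220.9-fold from 2 counts (60.9 to 1828.3). Immediate early genes rose in 10 of 14 and fell in 3 (2.34), with the phosphatase Dusp5 at 3.69. Interferon response genes rose in 11 of 16 (2.22), with the deconjugating enzyme Usp18 at least 36.5-fold higher. Of 16 p53 and senescence genes, 11 rose and 1 fell (1.56), led by Perp (6.13) and the cell-cycle inhibitors Cdkn2b (3.68) and Cdkn2a (3.21). Against WT ESC the p53 list median was -0.24, the interferon and AP-1 medians were 0.76 and 0.58, and of 16 immediate early genes 6 rose and 5 fell (0.44).

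Proliferation and chromatin genes moved down. Of 27 cell cycle genes, 20 fell and none rose (median -1.25), with cyclin D1, Ccnd1, at -3.51 and the replication helicase genes Mcm3 and Mcm2 at -2.06 and -2.03. Of 22 chromatin regulators, 12 fell and 1 rose (-1.14). The de novo DNA methyltransferase gene Dnmt3b fell 12.3-fold (10.4 to 14.6) and the corepressor gene Rcor2 8.86-fold (7.14 to 11.1), while the 5-methylcytosine oxidase gene Tet3 rose 28.3-fold (17.3 to 49.9). Of 16 glycolysis genes, 3 fell and 1 rose (-0.83), the riser being the glucose transporter gene Slc2a1 (2.24). Against WT ESC, 3 of 16 rose and 3 fell (0.03). Cholesterol synthesis genes fell in 5 of 18 and rose in 2 (-0.40). Of 8 ectoderm genes, 4 fell and 2 rose (-1.33). Of 5 mesoderm genes, 2 fell and 2 rose (0.36), with Eomes, a regulator of early mesendoderm, at -2.89.

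Of measured markers of other cell types, 3 of 3 macrophage genes rose (median 1.60), as did 3 of 4 skeletal muscle (2.86). The measured erythroid gene, Hba-a1, rose at least 7.0-fold. Most members of these lists were not measured. A marker low without doxycycline is measured only if it is high enough in the induced library. These counts therefore lean towards rises and cannot decide whether the lists rose as a whole. Of 4 endothelial markers, 2 rose and 1, Pecam1, fell (0.33). None of the 3 measured sex chromosome genes passed 2-fold (-0.34), and in the factors list 3 rose and 2 fell of 6 (0.12). The same rule between the uninduced line and WT ESC gave 672 genes higher and 1998 lower, and line, culture and depth cannot be told apart there. With no low filter the mesenchymal, endoderm and protease medians were 1.53, 1.21 and 1.01. Against both controls in the same direction, c-Jun left 1344 genes higher and 1276 lower. Neither control is labelled as given doxycycline, so effects of the drug and of c-Jun cannot be told apart in ESC. Total-count scaling shifted the median of all genes in this comparison by 0.19 and the authors' TPM scale by 0.36, and the latter gave 1163 lower genes.

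**Figure D2:**
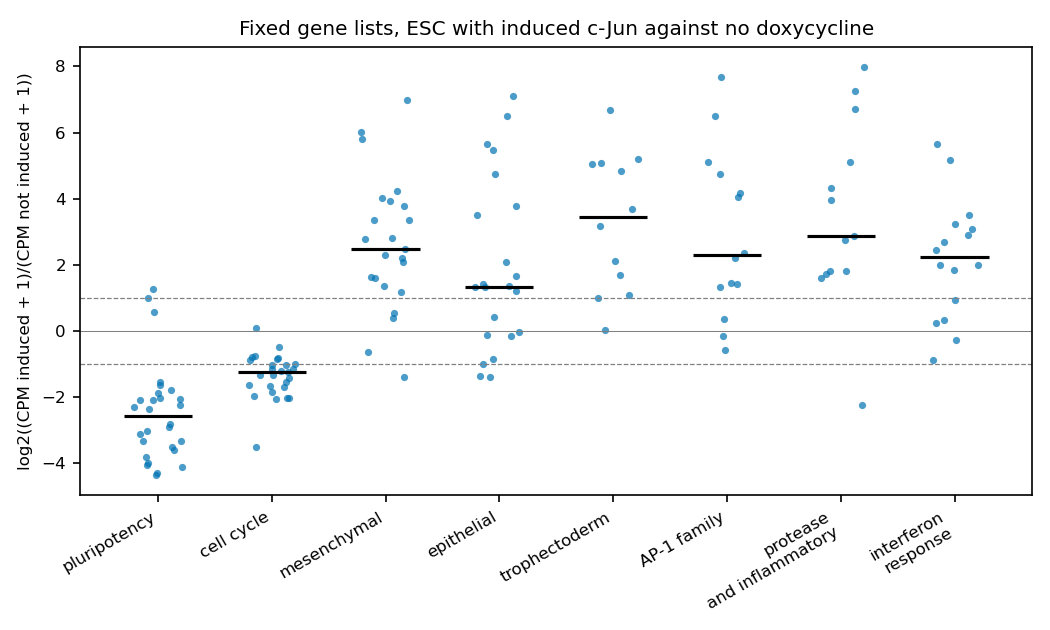
Change in induced against uninduced ESC (log2 ratio of CPM plus 1) for each measured member of 8 gene lists, 1 point per gene, with black bars at list medians and dashed lines at 2-fold. The pluripotency median lies at -2.58 and the trophectoderm median at 3.44.

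Over-expression in MEF asked what each factor does without the reprogramming factors. The DR library, the matched control, itself differed from WT MEF by 1048 genes higher and 1143 lower of 10964 measured, more than c-Jun, c-JunDN or Jdp2 differed from DR. All 26 interferon response genes rose in DR against WT MEF (median 3.82), among them the antiviral genes Isg15 (6.22), Ifit1 (5.89) and Oasl2 (5.63). The prostaglandin synthase gene Ptgs2 (-3.36) and the YAP target gene Ctgf (-2.92) fell.

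With c-Jun in MEF, all measured interferon response genes and many contractile, cholesterol and mesenchymal genes fell, while protease and inflammatory genes went both ways. Of 11114 measured genes, 861 rose and 1060 fell against DR, and 530 and 591 did so against WT MEF too. All 26 interferon response genes fell, with a median of -3.79, below all 10000 random lists. Oasl2 fell 72.8-fold (28.1 to 268.9), Ifit1 57.2-fold (29.9 to 125.8) and Mx2, with 1 count left, 133.5-fold (23.6 to 5311.2). Against WT MEF the median of the 12 measured interferon genes was -0.65, since WT MEF was also low.

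Of 34 mesenchymal genes, 14 fell, 1 rose and 19 did neither (median -0.91). The proteoglycan gene Lum fell 10.0-fold (6.95 to 14.9), the collagen cross-linking oxidase gene Lox 5.71-fold (5.29 to 6.16) and the growth factor receptor gene Pdgfrb 4.84-fold (4.07 to 5.80). Contractile genes fell in 11 of 16 (-1.36), with Myl9 at -3.12, Actg2 at -2.44 and Acta2, smooth muscle actin, at -2.25. Of 19 cholesterol synthesis genes, 11 fell and 1 rose (-1.02). Dhcr7, the last enzyme of the pathway, was at -1.75 and Insig1, a sterol sensor that restrains it, at 1.47. Col4a2 (-3.74) and Col4a1 (-3.53) led 4 falls among 8 endoderm genes (-1.11). Both rose with c-Jun in ESC. The growth factor gene Bmp4 fell to 0 counts, the Wnt-target receptor gene Lgr5 at least 48.1-fold and Egfl6 at least 43.9-fold. Fmod, a collagen-binding proteoglycan, fell 107.4-fold to 1 count (18.9 to 4279.4).

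Of 24 protease and inflammatory genes, 9 rose and 7 fell (0.28), and the median against WT MEF was -0.36. Serpinb2, a plasminogen activator inhibitor, rose 258.4-fold from 3 counts (88.1 to 1255.8), the stromelysin Mmp10 40.3-fold from 3 counts (13.5 to 198.3) and Il11 13.1-fold (6.12 to 33.6). The highest genes also included Rarres2, the chemerin gene (6.73), Sprr1a, a cornified-envelope precursor (6.49), the membrane protease Adam8 (6.03) and the glutathione transferase Gsta2, at least 44.1-fold. The AP-1 gene Fosl1 rose 12.1-fold (4.44 to 46.4). Klf4 fell 7.74-fold (5.32 to 11.6) and Myc rose 3.32-fold (2.48 to 4.49). The cell cycle median was 0.44 with 1 of 27 genes higher and 1 lower, and -0.17 against WT MEF. The immediate early median was 0.71 against DR and -0.57 against WT MEF.

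With c-JunDN in MEF, changes against DR were fewer, with falls in the protease and inflammatory list and rises among the measured macrophage markers. Of 11030 genes, 358 rose and 299 fell, with 173 and 143 against both controls, but 1170 and 1205 against WT MEF alone. Of 21 protease and inflammatory genes, 12 fell and 1 rose (median -1.04). The interleukin-33 receptor gene Il1rl1 fell 11.1-fold (7.62 to 16.8) and the chemokine gene Cxcl5 9.43-fold (5.02 to 19.6), while the gelatinase gene Mmp9 rose 6.79-fold (2.90 to 19.4). Of 16 glycolysis genes, 5 fell and none rose (-0.72), with Slc2a1 at -1.64 and the enolase gene Eno1 at -1.22. Mesenchymal genes stayed mostly within 2-fold of DR, with 4 of 34 lower and 1 higher (-0.05). Against WT MEF, though, 14 were lower and 3 higher (-0.85). Against DR, the metastasis-associated calcium-binding gene S100a4 fell 3.71-fold (3.24 to 4.26). Pdgfra, the gene of platelet-derived growth factor receptor alpha, fell 5.00-fold (4.32 to 5.80). The highest genes were the hypertrophic-cartilage collagen Col10a1 (4.43), the ATP-gated channel P2rx3 (3.77) and the protease Pappa2 (3.76), and Acta1, skeletal actin, rose 11.9-fold (8.22 to 17.9). The metalloreductase Steap4 fell at least 14.9-fold, Ptprn 17.3-fold (8.84 to 38.6) and the activin subunit gene Inhbb 8.56-fold (6.43 to 11.6). The interferon median was -0.03 against DR and 3.30 against WT MEF. Of 10 measured macrophage markers, 5 rose (1.13), among them the complement gene C1qc at 1.61. A marker low with DR is measured only if it is high enough in the c-JunDN library, so this count leans towards rises.

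With Jdp2 in MEF, most protease, inflammatory and glycolysis genes fell, and 13 of 26 interferon response genes rose. Of 11080 genes, 644 rose and 700 fell, with 418 and 461 against both controls, but 1316 and 1609 against WT MEF alone. Of 21 protease and inflammatory genes, 13 fell and 2 rose (-1.72). Il1rl1 fell 24.9-fold (13.7 to 50.5), Mmp3 at least 11.3-fold and Cxcl5, with 1 count left, 85.2-fold (14.9 to 3401.8). Glycolysis genes fell in 11 of 16 (-1.36), with Tpi1, Pfkl and Eno1 at -1.81, -1.81 and -1.72. No interferon gene fell (median 0.99), with Ifi44 at 2.32 and the tetherin gene Bst2 at 2.02, and the median against WT MEF was 4.70. Eln, the elastin gene, rose 109.1-fold (90.7 to 132.5) to 5962.9 CPM, Postn, periostin, 5.16-fold (4.96 to 5.38), and the prostaglandin-degrading gene Hpgd 120.4-fold from 2 counts (33.0 to 999.8). Postn was the riser among 34 mesenchymal genes, 10 fell and 23 did neither (-0.21, or -1.01 against WT MEF), the falls including Loxl2 (-2.32) and Lum (-1.89). Bmp4 rose 3.75-fold (2.82 to 5.05), the mirror of its fall with c-Jun. The retinoic-acid-binding gene Crabp1 fell 53.6-fold (36.4 to 82.3) and Il1rn, the interleukin-1 receptor antagonist, 61.0-fold to 2 counts (16.5 to 509.0). Fosl2 fell 6.72-fold (5.29 to 8.65) and Tubb3, a neuronal tubulin gene, 15.2-fold (6.71 to 42.4). Of 19 cholesterol synthesis genes, 3 fell and none rose (-0.56). The immediate early median was 0.55 against DR and -0.39 against WT MEF.

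With Oct4 in MEF, pluripotency genes other than Pou5f1 did not follow, while many mesenchymal and interferon genes fell and most measured macrophage markers rose. Of 11177 genes, 1294 rose and 1147 fell, with 824 and 688 against both controls. Of 7 measured pluripotency genes, 1 rose, Pou5f1 itself, and 1 fell (-0.13). Mesenchymal genes fell in 16 of 34 and rose in 6 (-0.84), with the collagen Col6a1 at -2.48, the repressor Snai1 at -2.31 and the gelatinase Mmp2 at -2.01. Pdgfra fell 49.1-fold (31.3 to 81.9) and the angiotensin receptor gene Agtr2 525.2-fold to 1 count (93.9 to 20783.1). The small matrix proteoglycan gene Aspn fell 144.1-fold to 3 counts (49.0 to 701.2), the growth factor gene Ptn 75.7-fold (55.7 to 105.7) and Clca1 at least 138.9-fold. The highest genes included the synaptic organiser Cbln2, at least 170.3-fold, the ephrin receptor Epha5, 332.8-fold from 2 counts (91.8 to 2753.9), the neurofilament Nefm, 176.9-fold (75.5 to 546.1), and the integrin ligand Npnt (6.92). Of 5 ectoderm genes, 1 rose and 1 fell (0.19), the riser being Mtap2, a neuronal microtubule-binding protein, 18.1-fold (13.9 to 24.0). Cell cycle genes rose in 4 of 27 (0.64), with Rrm2 at 1.99, and against WT MEF none rose (0.10). Interferon genes fell in 18 of 25 against DR (-1.58), and 18 of 21 rose against WT MEF (1.94). Of 12 measured macrophage markers, 11 rose (2.23), including Csf1r, the macrophage growth factor receptor (2.72), and C1qc (2.61). That count leans towards rises too, since a marker low with DR must be high enough with Oct4 to be measured. This library was quantified by the authors on another gene annotation, and Taf9, at 0 counts in it (at least 53.9-fold lower), is uncertain for that reason.

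**Figure D3:**
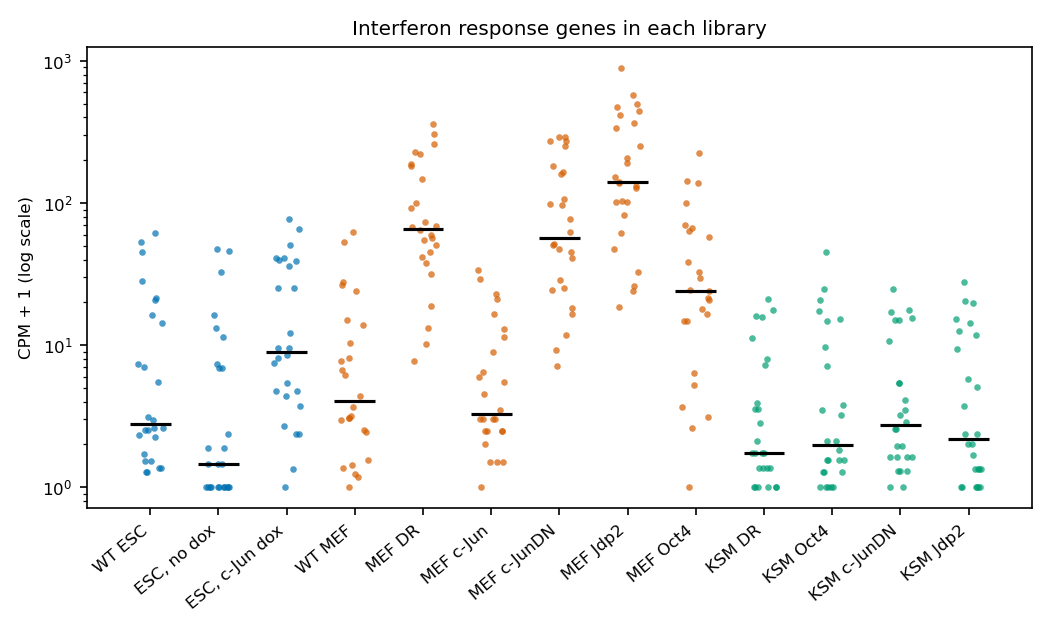
Level of the interferon response genes (CPM plus 1, log axis) in each RNA library, 1 point per gene, with bars at medians. Medians are 3.02 CPM in WT MEF, 65.05 with DR, 2.25 with c-Jun, 56.0 with c-JunDN, 138.9 with Jdp2 and 23.0 with Oct4.

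In reprogramming, each factor was added to KSM to ask what stands in for Oct4 by day 3. With Oct4, part of the pluripotency list rose, and part of the mesenchymal and epithelial lists fell. Of 10750 genes, 500 rose and 717 fell against KSM with DR. Of 13 measured pluripotency genes, 7 rose, 1 fell and 5 did neither (median 1.43, above all 10000 random lists). The risers include the introduced Pou5f1, and the list also holds the introduced Sox2 and Klf4. The ESC transcription factor gene Tcfcp2l1 rose 21.8-fold (9.81 to 60.2) and L1td1 238.9-fold from 1 count (42.6 to 9466.3). Mesenchymal genes fell in 12 of 34 and none rose (-0.69), with Thy1, a fibroblast surface marker, at -1.65, Lox at -1.62 and S100a4 at -1.60. Of 9 epithelial genes, 5 fell (-1.05), led by Krt19, 19.0-fold (12.8 to 29.1), and Krt8, 13.5-fold (11.3 to 16.2). All 3 measured keratinocyte markers fell as well, Krt6a at -3.64, Sfn at -2.50 and Krt14 at -2.30. Immediate early genes fell in 5 of 13 (-0.85), and protease and inflammatory genes in 5 of 18 (-0.67), with the epidermal growth factor receptor ligand Hbegf at -1.83. Jun fell 2.38-fold (1.86 to 3.07) and Ccnd1 2.12-fold (2.00 to 2.25), while the cell cycle median was 0.37. The imprinted placental gene Peg10 rose 8.95-fold (6.68 to 12.2) and the ectonucleotidase Nt5e 48.3-fold (29.6 to 84.9). Aoah, a lipase that inactivates endotoxin, rose at least 52.9-fold and Dmrtc2 at least 40.3-fold. The Wnt antagonist Nkd1 fell 27.6-fold (13.7 to 65.0) and the carboxylesterase Ces1f 16.0-fold (13.0 to 19.9).

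With c-JunDN or Jdp2 added to KSM, most pluripotency and mesenchymal genes stayed within 2-fold of the control. c-JunDN gave 194 genes higher and 174 lower of 10715, and Jdp2 gave 288 and 141 of 10763. None of 7 measured pluripotency genes rose with c-JunDN (median 0.01). With Jdp2 the only riser of 7 was Pou5f1 (median -0.01), 2.58-fold higher (1.26 to 5.70) at 10.5 CPM. With c-JunDN Pou5f1 was 2.17-fold higher (1.05 to 4.84), below 2-fold on the log2 scale used here. Mesenchymal genes rose in 5 of 34 with c-JunDN (0.37) and in 4 of 34 with Jdp2 (0.36), where Twist2 fell (-1.05). Lox, Lum and Dcn were at 1.35, 1.27 and 1.22 with c-JunDN, and Acta2 and Col1a2 at 1.54 and 1.28 with Jdp2. Il1rl1 rose with both, 3.46-fold (2.10 to 5.96) with c-JunDN and 3.03-fold (1.81 to 5.27) with Jdp2, whereas it fell with both in MEF. Krt19 fell 3.81-fold (3.09 to 4.72) and Krt8 2.59-fold (2.36 to 2.85) with c-JunDN, and were at -0.46 and -0.44 with Jdp2. All 3 measured keratinocyte markers fell with c-JunDN (median -1.70), Krt6a by 8.59-fold (4.68 to 17.3), while with Jdp2 1 of 5 rose and 1 fell (-0.10). The p-cadherin gene Cdh3 rose with both (1.78 and 1.98), as did the chemokine receptor gene Cxcr4 from 3 counts, 4.84-fold (1.40 to 25.8) and 6.11-fold (1.81 to 32.1). The cell cycle median was 0.21 with c-JunDN and -0.27 with Jdp2, where Cdkn1a, the p21 inhibitor, was at 0.71. The lowest value with c-JunDN belonged to Lars2, at 10895.0 CPM with DR, 237.2 with c-JunDN and 844.9 with Jdp2. Ribosomal RNA-like reads can fall on Lars2, so it is uncertain, as are Amd1, Mndal and Moap1, which have close copies or overlapping genes. A pseudocount of 5 left 46 genes higher and 95 lower with c-JunDN, and 100 and 65 with Jdp2.

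**Figure D4:**
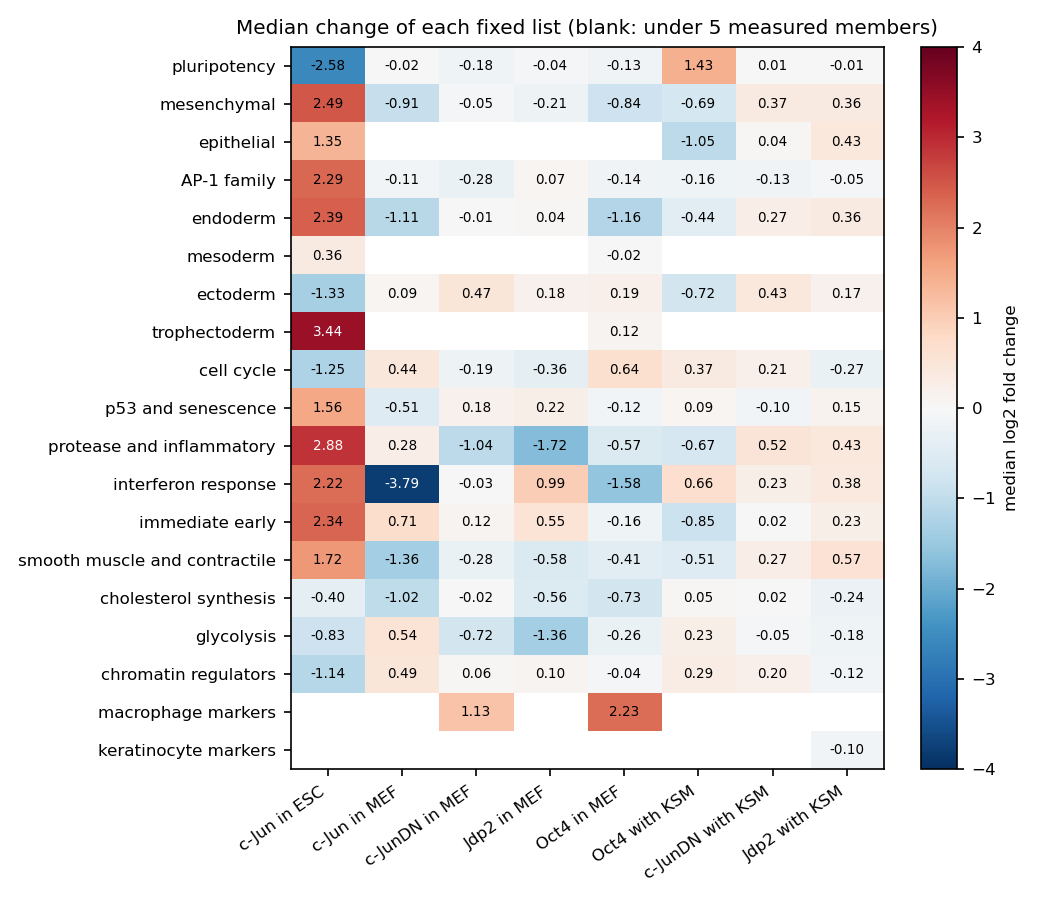
Median log2 change of each fixed gene list (vertical axis) in each of 8 comparisons with the matched control (horizontal axis), with colour giving the median and blanks where under 5 members were measured. The interferon median is -3.79 with c-Jun and 0.99 with Jdp2 in MEF, and the pluripotency median is -2.58 with c-Jun in ESC.

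Genes that set MEF apart from ESC were followed in each comparison. At least 8-fold separated WT MEF from WT ESC in 909 MEF-enriched and 756 ESC-enriched genes. With c-Jun in ESC, 406 of 525 measured MEF-enriched genes rose (median 2.31, or 1.24 with no low filter) and 367 of 647 ESC-enriched genes fell (-1.19). Both changes are against the uninduced line, and against WT ESC the mesenchymal list median with c-Jun was 0.19. Identity genes were not set against WT ESC, from which they were picked. With c-Jun in MEF, 303 of 882 MEF-enriched genes fell and 89 rose (-0.43). Of 220 ESC-enriched genes, 49 rose and 35 fell (0.34), but with 32-fold identity genes 4 of 23 rose and 6 fell (-0.12). With Oct4 in MEF, 253 of 877 MEF-enriched genes fell and 129 rose (-0.25), and 83 of 238 ESC-enriched genes rose and 30 fell (0.60). For c-JunDN and Jdp2 in MEF the MEF-enriched medians were 0.03 and -0.19 and the ESC-enriched medians 0.02 and 0.04. With Oct4 in KSM, 191 of 686 MEF-enriched genes fell (-0.48) and 65 of 346 ESC-enriched genes rose (0.38). With c-JunDN and Jdp2 in KSM the MEF-enriched medians were 0.12 and 0.11 and the ESC-enriched medians 0.20 and 0.03.

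Likeness between factors was measured as correlations of log2 changes across genes, which are not independent replicates, over 13 pairs. The highest correlations were those of c-JunDN and Jdp2, in KSM (Pearson r 0.61, Spearman rho 0.52) and in MEF (0.48 and 0.43). Unchanged groups sharing the control gave a simulated r of 0.52 in KSM and 0.51 in MEF. Every MEF pair lay below its simulated r. Changes particular to 1 factor lower r and are absent from the simulation, so r cannot be judged against it. In KSM, 113 genes rose with both factors, where independent lists would share 5.6, and 67 fell with both, where they would share 2.39. In MEF, 185 rose and 188 fell with both, where independent lists would share 22.5 and 19.9. Opposite ways went 4 genes in KSM and 28 in MEF, against 7.63 and 42.9. The covariance was 0.115 in KSM and 0.197 in MEF, beside 0.045 and 0.06 simulated for unchanged groups sharing the control. c-Jun and Jdp2 in MEF gave r of -0.02 and rho of -0.02, beside a simulated r of 0.5, and a covariance of -0.017 beside 0.062. In that pair 132 genes rose and 203 fell together against 51.1 and 74.5 for independent lists, and 361 went opposite ways against 124.0. c-Jun and c-JunDN in MEF gave 0.22 and 0.20 (0.114 beside 0.061), with 154 genes higher and 134 lower in both against 29.6 and 30.9, and 109 opposite against 62.1. With the second factor of the pair set against WT MEF, r was -0.19 for c-Jun and c-JunDN, 0.15 for c-JunDN and Jdp2 and -0.28 for c-Jun and Jdp2.

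Oct4 in MEF gave r of 0.29 with c-Jun (rho 0.23, covariance 0.328 beside 0.066, the largest excess of the pairs sharing a control), 0.25 with c-JunDN (0.26, 0.156 beside 0.065) and 0.21 with Jdp2 (0.21, 0.185 beside 0.067). With Oct4 set against WT MEF these were 0.04, 0.07 and 0.12. In those pairs 332, 187 and 225 genes rose together against 112.0, 45.1 and 80.1 for independent lists, and 423, 141 and 291 fell against 119.0, 35.8 and 80.6. Opposite ways went 272, 111 and 256 against 233.0, 80.4 and 161.0. Oct4 in KSM gave 0.30 with c-JunDN (0.32, 0.096 beside 0.045) and 0.13 with Jdp2 (0.11, 0.042 beside 0.046). With c-JunDN 67 genes rose and 92 fell together against 9.86 and 12.2, with 39 opposite against 22.9, and with Jdp2 69 and 64 against 14.3 and 10.4, while 80 went opposite ways against 28.9. The same factor in MEF and in KSM gave 0.07 for Oct4, 0.08 for c-JunDN and 0.10 for Jdp2 (rho 0.02, 0.05 and 0.10). c-Jun in MEF and in ESC gave 0.06 (rho -0.03). Part of the excess within MEF or within KSM may come from the shared control.

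The peak lists of c-Jun in induced ESC and of c-JunDN in reprogramming shared few sites. Of 1340 c-JunDN peaks, 45 (3.36%, exact 95% interval 2.46 to 4.47) overlapped a c-Jun peak (0.896% with 50% reciprocal overlap), and 44 of 3100 c-Jun peaks (1.42%) overlapped a c-JunDN peak. Shifting the c-JunDN list by 10 fixed distances left 0 to 4 overlaps, 1.7 on average. The highest c-Jun peaks, at mm9 chromosome 3, 34549318 to 34550375, and chromosome 4, 55542620 to 55543907, had a score of 3100, and the next had 449.92 (chromosome 17, 66310715 to 66311658), 329.38 (chromosome 16, 10754430 to 10755134) and 289.57 (chromosome 15, 61820895 to 61821479). The peaks on chromosomes 17 and 15 overlapped c-JunDN peaks. It was not tested whether 3100 is a ceiling of the score, nor whether DNA of the introduced vectors contributes to the peaks on chromosomes 3, 4 and 15, which limits what the overlap on chromosome 15 means. The highest c-JunDN peaks lay on chromosome Y, 2891831 to 2892481 (258.11), chromosome 17, 13744767 to 13744854 (256.12), chromosome 17, 87970990 to 87971233 (229.08), chromosome 4, 140255514 to 140255776 (226.08), and chromosome 11, 3041825 to 3045467 (213.73). Median widths were 419 bp for c-Jun and 143 bp for c-JunDN. There is 1 list per factor, in different cells, so the factor and the cell type cannot be separated. The antibody is labelled c-Jun for the c-JunDN sample too. Whether the c-JunDN list also holds sites of endogenous c-Jun was not tested.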

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

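All tests of explanations below except that of the gene annotation were chosen after the result was seen. Each result here was set apart because a list moved by at least 0.5 one way in one cell type and the opposite way in another under the same factor. These differences were not tested, since each rests on 1 library per side.

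The interferon response list differed by 6.01 between c-Jun in ESC (2.22) and c-Jun in MEF (-3.79). A raised response in the DR library alone would leave the c-JunDN and Jdp2 libraries near WT MEF, but their medians against WT MEF were 3.30 and 4.70, which argues against it. The weakest median under the other scalings was -3.75, which argues against library scaling. Fewer vector-carrying cells in the c-Jun culture could lower a response to the vector, and Jun was 3.02 times as high in the c-Jun as in the c-JunDN library, which leaves this open. A repression by c-Jun itself likewise stays open.

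The mesenchymal list differed by 3.40 between c-Jun in ESC (2.49) and in MEF (-0.91). Fibroblasts in the induced culture would bring their abundant transcripts, and the called genes reached a median of 10.4% of the WT MEF level. Of 8 genes at 5000 CPM or more in WT MEF, 6 stayed below that share divided by 3, among them Col1a2 (0.0545%), Col3a1 (0.0571%) and Fn1 (2.45%), with Sparc (22.2%) and Col5a1 (6.43%) above, which argues against fibroblasts as the whole cause. Library scaling left a weakest median of 2.47, which argues against it as well. A response of ESC to c-Jun stays open, and the median against WT ESC was 0.19, but WT ESC held the 8 genes at uneven shares of the WT MEF level (Acta2 0.153%, Col5a2 1.68%, Col1a1 1.76%, Col1a2 1.79%, Col5a1 2.95%, Sparc 4.88%, Col3a1 5.56% and Fn1 12.8%), and fibroblasts in that culture were not tested.

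The interferon list differed by -2.24 between Oct4 in MEF (-1.58) and Oct4 in KSM (0.66). The KSM value rests on fewer measured members, and the list was low there, at 0.74 CPM with DR and 0.97 with Oct4. Against WT MEF the MEF median was 1.94, but DR alone already raised the list (65.05 CPM against 3.02 in WT MEF). Its sign is therefore not comparable with that in KSM, which is against DR. The Oct4 MEF library was quantified on another annotation, and 397 of its 2441 called genes (16.3%) lay at least 2-fold outside the range of all other libraries. That share was 9.07% for c-Jun (179 of 1974), 13.7% for Jdp2 and 3.47% for c-JunDN, which leaves the annotation open as a cause of some calls. Macrophages in the Oct4 culture might explain its macrophage markers, of which 10 of 12 were at least 2-fold above both DR and WT MEF. That count uses the same markers whose rise is to be explained, so it cannot decide. No biological explanation was tested for these markers.

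The endoderm list differed by 3.50 between c-Jun in ESC (2.39) and in MEF (-1.11). The p53 and senescence list differed by 2.07 (1.56 and -0.51), but against WT ESC the ESC median was -0.24, the same sign as in MEF. The smooth muscle and contractile list differed by 3.08 (1.72 and -1.36). The glycolysis list differed by -1.37 (-0.83 and 0.54), and against WT ESC the ESC median was 0.03. The protease and inflammatory list differed by -1.56 between c-JunDN in MEF (-1.04) and in KSM (0.52). The contractile list differed by -1.15 between Jdp2 in MEF (-0.58) and in KSM (0.57).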

How the results depend on the processing

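Of the alternatives run, 772 values stayed within the band set for their kind, here called the same, 110 moved and 5 reversed. The same does not mean equal. With total counts, c-Jun in ESC had 2820 genes higher and 1550 lower, against 2392 and 2108 reported, and was called the same. List medians were the same in 129 of 129 cases under median-ratio scaling, 127 under total counts, 121 under TPM, 124 with no filter, 126 with a pseudocount of 5 and 45 of 79 with the WT control. The alternatives without synonym matches (1193 higher, 1077 lower) and without outlying genes (983 and 1061) for Oct4 in MEF were chosen after seeing the data and left the counts within 1.5 times. For the peaks, midpoints within 1 kb and the upper part by score gave the same. Changes of genes within 10 kb of a peak, and their variants at 1 kb, at 50 kb and with the upper part by score, were not run. The cause of the moves was not tested, except that fewer genes pass 2 controls or a larger pseudocount by construction. Depth limits folds to counts above a floor of 0.835 to 1.6 CPM in the libraries other than WT.

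With the WT control, the counts were 1316 higher and 1609 lower for Jdp2 in MEF and 1170 and 1205 for c-JunDN. In ESC with c-Jun the medians were 0.58 (AP-1), 0.03 (glycolysis), 0.76 (interferon), 0.19 (mesenchymal) and -0.24 (p53, reversed). For c-Jun in MEF they were -0.17 (cell cycle), 0.06 (chromatin), 0.34 (glycolysis), -0.57 (immediate early, reversed), -0.65 (interferon) and -2.34 (contractile). For c-JunDN in MEF they were -0.89 (cell cycle), -0.34 (cholesterol), -0.35 (chromatin), -0.44 (endoderm), -0.76 (immediate early), 3.30 (interferon), -0.85 (mesenchymal), 0.64 (p53) and -1.0 (contractile). For Jdp2 in MEF they were -1.04 (cell cycle), -0.48 (chromatin), -0.39 (immediate early, reversed), 4.70 (interferon), -1.01 (mesenchymal), 0.41 (p53), -2.67 (protease) and -1.38 (contractile). For Oct4 in MEF they were 0.10 (cell cycle), -0.39 (chromatin), -1.71 (endoderm), -0.80 (immediate early), 1.94 (interferon, reversed) and -1.02 (contractile).

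Against both controls, genes higher and lower were 1344 and 1276 for c-Jun in ESC, 530 and 591 for c-Jun in MEF, 173 and 143 for c-JunDN, 418 and 461 for Jdp2 and 824 and 688 for Oct4. With the second factor against WT MEF, the correlations were -0.19 for c-Jun and c-JunDN (reversed), -0.28 for c-Jun and Jdp2, 0.04 for c-Jun and Oct4, 0.15 for c-JunDN and Jdp2, 0.07 for c-JunDN and Oct4 and 0.12 for Jdp2 and Oct4. At 20 CPM or more they were 0.17 for c-Jun and c-JunDN, -0.11 for c-Jun and Jdp2, 0.26 for c-Jun and Oct4, 0.23 for c-JunDN and Oct4 and 0.19 for Jdp2 and Oct4 in MEF, 0.08 for Oct4 and Jdp2 in KSM, and between MEF and KSM 0.14 for Jdp2, 0.10 for Oct4 and 0.10 for c-JunDN.

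With no low filter, genes higher and lower were 672 and 466 for c-JunDN in MEF, 459 and 303 for c-JunDN in KSM and 684 and 266 for Jdp2 in KSM, and genes higher were 996 for Jdp2 in MEF and 792 for Oct4 in KSM. Medians were 1.21 (endoderm), 1.53 (mesenchymal) and 1.01 (protease) for c-Jun in ESC, and for endoderm in KSM 0.07 with Jdp2 and 0.06 with c-JunDN. ESC-enriched medians were -1.07 for c-Jun in ESC, 0.15 for Oct4 and 0.10 for c-JunDN in KSM, and the MEF-enriched median for c-Jun in ESC was 1.24. With a pseudocount of 5, genes higher and lower were 176 and 156 for c-JunDN in MEF, 46 and 95 for c-JunDN in KSM, 100 and 65 for Jdp2 in KSM and 277 and 455 for Oct4 in KSM, with 463 lower for Jdp2 in MEF. Medians were -3.09 (interferon, c-Jun in MEF), 1.45 (macrophage, Oct4 in MEF) and 0.80 (macrophage, c-JunDN in MEF). Correlations were 0.11 for Oct4 and Jdp2 in KSM, -0.04 for c-Jun and Jdp2 in MEF and 0.59 for c-JunDN and Jdp2 in KSM.

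With TPM, 1163 genes were lower for c-Jun in ESC. Medians were -0.87 (cell cycle) and -0.03 (cholesterol) for c-Jun in ESC, 0.86 (cell cycle) and 0.24 (chromatin) for Oct4 in MEF, -0.13 (cholesterol), -0.07 (glycolysis) and 0.33 (immediate early) for Jdp2 in KSM and 0.00 (glycolysis) for c-JunDN in KSM. With total counts they were -0.15 (cholesterol) and -0.09 (glycolysis) for Jdp2 in KSM. With median-ratio scaling the MEF-enriched median for c-JunDN in KSM was 0.06. The median of all genes shifted by 0.19 (total counts) and 0.36 (TPM) for c-Jun in ESC, and with TPM by 0.17 for Oct4 in MEF and 0.11 for Jdp2 in KSM. The share of calls that were higher, 53.2% for c-Jun in ESC, was 64.5% with total counts, 72.6% with TPM and 39.2% with the WT control. It was 66.4% with TPM for Oct4 in MEF, and went from 52.7% to 32.6% with a pseudocount of 5 for c-JunDN in KSM.

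With 32-fold identity genes, MEF-enriched medians were 2.90 for c-Jun in ESC and -0.74, 0.29 and 0.26 for Oct4, c-JunDN and Jdp2 in KSM. ESC-enriched medians were -1.76 for c-Jun in ESC and 0.27 and 0.10 for c-JunDN and Jdp2 in KSM. In MEF the MEF-enriched medians were -0.91 for c-Jun, -0.02 for c-JunDN, -0.47 for Jdp2 and -0.59 for Oct4. The ESC-enriched medians there were -0.12 for c-Jun, 0.06 for c-JunDN, 0.38 for Jdp2 and 0.66 for Oct4. These MEF values are not in the counts of moved and reversed values above. With 50% reciprocal overlap, 0.896% of c-JunDN peaks overlapped a c-Jun peak.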

Other observations

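The uninduced ESC line differed from WT ESC in mesenchymal genes, of which 19 of 25 were lower and 1 higher (median -1.97), and in single genes far apart in level. Dnmt3l, a cofactor of DNA methylation, was 62.3-fold higher (50.2 to 78.1) in the uninduced line, the RNA-binding gene Lin28a 32.3-fold (27.2 to 38.5) and the chromatin gene Utf1 27.5-fold (22.6 to 33.7). Trh, a hormone precursor, was higher by 6.70 on the log2 scale and the epiblast growth factor gene Fgf5 at least 52.4-fold. The collagen gene Col3a1 was 160.7-fold lower (68.8 to 495.1) than in WT ESC, and the matrix gene Postn at least 43.4-fold lower. The immediate early genes Fos and Egr1 were at least 48.9-fold and, with 1 count left, 407.0-fold (73.0 to 16082.2) lower. Of 29 pluripotency genes 8 rose and 7 fell (median 0.08).

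Single genes that moved in 1 or more cultures were chosen after their values were seen. Csf1r, the macrophage growth factor receptor gene, rose with c-Jun in ESC, from 0 counts to 74.6 CPM, and in MEF, 16.8-fold (8.59 to 37.4), while the macrophage lysozyme gene Lyz2 fell 2.65-fold (1.88 to 3.80) in MEF. Mtap2 rose in MEF with c-JunDN (1.32), Jdp2 (2.18) and Oct4 (4.13), but was at 0.09 with c-Jun. Il1rl1 fell in MEF with c-JunDN, Jdp2 and Oct4 (-3.37, -4.41 and -4.03) and was at 0.22 with c-Jun. Hbb-y, an embryonic globin gene, rose 2.66-fold (2.10 to 3.39) with Oct4 in KSM and fell 2.48-fold (1.69 to 3.69) with Jdp2. Krt5, a basal keratinocyte gene, was 27.5-fold higher with Jdp2 in KSM, from 1 count (4.57 to 1122.3).

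The c-Jun list had 5 peaks on chromosome X and 0 on Y, and the c-JunDN list 35 (2.61%) and 21 (1.57%). The peak numbers of the c-JunDN list reached 1516, with 176 numbers absent.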
